A study of Mus musculus with 6 samples.

How the data were processed

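RNA-seq was made from sorted epithelial cells of the small intestine of C57BL/6 mice, 2 libraries each from specific pathogen free (SPF), germ-free (GF) and antigen-free (AF) mice. Per the labels, RNA was purified with RNeasy columns, libraries were prepared with a TruSeq RNA kit from total RNA, and sequencing was on a NextSeq instrument. Groups were taken from the sample labels. The submitters' processing notes name STAR 2.5.2b, RSEM, edgeR 3.16.5 and the GRCm38/mm10 mouse genome. The version of RSEM, the annotation release, any read filters and the strand setting are not given in the sources used here. Each library has its own table of RSEM gene results. Per the file headers, the authors deposited expected counts per gene, in which RSEM splits reads that fit several genes by estimate, with no scaling between libraries. TPM values, which RSEM scales by effective length and to a fixed total per library, were deposited in the same tables per the file headers. Counts of near-identical genes, between which RSEM splits reads, are uncertain. RSEM's posterior standard deviation, the largest over libraries with at least 10 counts, was 22.5% of the count for Hist1h2bk and at most 2.31% for the other genes named in the report, including H2-K1, H2-Q1 and H2-Q10 of MHC class I. With no strand setting given, reads of Pkd1l2 cannot be told from those of its antisense gene Gm15395.

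Expected counts were rounded to whole numbers, 23.5% of the values above 0 not being whole. The tables list 51912 genes, of which 51633 matched a symbol in a GENCODE M21 annotation of GRCm38, the source of all symbols and 1-based coordinates here. IDs without a symbol held at most 0.0842% of a library's counts. edgeR's filterByExpr at its defaults left 13644 genes. Libraries totalled 16109488 to 19417054 expected counts, so that 1 count was worth 0.0365 to 0.0785 CPM, with 11719 to 13734 genes at 10 counts or more. TMM factors were 0.791 to 1.41, the 20 most abundant genes held 29.3 to 54.9% of the counts, and pseudogenes of mitochondrial genes 8.35 to 16%. Libraries of a group differed far beyond sampling noise, with a chi-square per gene of 324 (SPF), 427 (GF) and 80.9 (AF) over genes with 20 counts or more per pair, so none was counted as a duplicate.

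The main test was edgeR's quasi-likelihood F test with all 6 libraries in 1 fit (estimateDisp, then glmQLFit with legacy on and robust off), which left 3 residual degrees of freedom, a common biological coefficient of variation of 0.368 and a prior of 3.08 degrees of freedom. The contrasts were GF versus SPF, AF versus GF and AF versus SPF, with an F test for any difference among the groups. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. Levels are CPM on TMM-scaled totals. Where a group had 0 counts, a fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 4 counts, the ratio has an exact binomial counting interval at 95%. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (1.17.8).

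Before the data were examined, 31 gene lists with 723 members were fixed: presentation by MHC class I and II, interferon response, host defence, xenobiotic metabolism, aryl hydrocarbon receptor targets, nutrient and bile acid handling, retinoid metabolism, amino acid stress, the clock, proliferation, epithelial cell types, small intestinal regions, immune, stromal and pancreatic cells, dissociation stress and sex-linked genes. Each was tested with limma's camera at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, and adjusted over the lists of a comparison. The list of pancreatic enzymes had only 2 genes past the filter, below the minimum of 3, and was not tested. Members were also adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. The rule for named genes, fixed at the same time, took up to 8 genes per direction past the threshold with at least 5 CPM and both libraries of a group apart, Ciita, Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, B2m, H2-K1, Tap1, Psmb8 and Nlrc5 in any case, up to 4 members past the threshold of each called list, otherwise at most 2 members of a list with the smallest p, and, where fewer than 3 genes passed, the 5 with the smallest p. Predicted genes and immunoglobulin or T cell receptor segments were not named under its first part.

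The alternatives were DESeq2's Wald test, edgeR's likelihood ratio test, robust and newer quasi-likelihood fits, median-of-ratios scaling, library totals alone, no low-count filter, a filter of 1 CPM in 2 libraries, limma on log2(TPM + 1) for genes with a TPM of at least 1 in 2 libraries, effective lengths as offsets, only the 2 groups compared, the 20 most abundant genes left out, an adjusted p below 0.1, an added 2-fold threshold, and each library left out in turn. With a library left out its group has 1, which is assumed to vary like the others. A covariate added after seeing the data was a crypt score, the mean centred log2 CPM of the Paneth, stem cell and proliferation lists per library. Fold changes against the shared SPF libraries were set beside 100 simulations. In these GF and AF were drawn around the mean of all libraries. The pipeline was tested on simulated counts for AF versus GF with 13244 genes. It called 2% of 50 genes changed 2-fold, 48% of 50 changed 4-fold, 98% of 50 changed 16-fold and 100% of 50 changed 64-fold, all in the right direction, with 9 unchanged genes called. The changed genes were drawn from those above a mean log2 CPM of 2, so these shares do not cover genes at lower levels. The MHC class I list, shifted by 1 log2 unit, had a camera adjusted p of 6.72e-08. Simulated genes were drawn independently, while the estimated correlation of this list in the data was 0.392. This step therefore cannot judge camera on correlated lists. The effective lengths were used only as offsets, and RSEM's posterior values only to judge shared reads. Each group's tables carry a date-like mark of their own, so a batch by date and the group cannot be told apart.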

Results

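RNA was sequenced from sorted small intestinal epithelial cells of C57BL/6 mice raised in 3 ways. Specific pathogen free (SPF) mice were free only of particular pathogens, germ-free (GF) mice had no microbiota, and antigen-free (AF) mice met foreign antigens from neither a microbiota nor their food. Each group had 2 libraries, named here by the numbers in their titles: SPF replicates 3 and 4, GF replicates 1 and 3, and AF replicates 2 and 3. The series asks how dietary antigens bear on antigen presentation by this epithelium. GF versus SPF compares mice without and with a microbiota, AF versus GF adds the removal of food antigens where there is no microbiota, and AF versus SPF takes both together. The composition of the diets is not given in the sources used here, and each group carries a date-like mark of its own. Other differences of diet, or a batch by date, therefore cannot be told apart from an effect of food antigens. The libraries held 17537299, 17703560, 19417054, 16917319, 16109488 and 16873652 expected counts in the order just given, so that a floor of 3 counts stood at 0.109 to 0.236 CPM, the count scaled to a library's normalised total. Levels are CPM, mean ± SD (n = 2 libraries), and positions are on GRCm38. Nothing in the labels says that the samples came from separate animals, so p-values measure only the spread between these samples, and floors and counting intervals cover counting error only.

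The libraries differed in their cell make-up within groups as well as between them. SPF replicate 4 was poor in markers of the crypt and also of goblet, tuft and enteroendocrine cells. Its centred median log2 level was -4.68 for the Paneth cell list, -2.29 for crypt stem cells and -2.13 for proliferation. In SPF replicate 3 these were 0.61, 0.69 and 0.95. For goblet, tuft and enteroendocrine cells the levels were -2.01, -2.56 and -2.68 in SPF replicate 4, against 1.16, -0.45 and -0.18 in SPF replicate 3. GF replicate 3 carried more lymphocyte RNA than GF replicate 1, with a summed level of the intraepithelial lymphocyte and T cell list of 496 against 55.1 CPM. The same sum was 299 and 122 CPM in SPF replicates 3 and 4, and 34.1 and 23.1 CPM in AF replicates 2 and 3. Sex-linked transcripts differed between groups too: the 4 Y-linked genes listed, Ddx3y, Eif2s3y, Kdm5d and Uty, were at 0 counts in both SPF libraries and present in the 4 others. Xist, the X-inactivation RNA of females and chosen here after its values were seen, stood at 129.7 and 96.6 CPM in SPF, 0.109 and 14.8 CPM in GF replicates 1 and 3, and 0 and 0.178 CPM in AF. GF replicate 3 thus held both Xist and Y-linked RNA. By these transcripts the SPF libraries read as female, and GF replicate 1 and both AF libraries as male. In GF versus SPF and AF versus SPF, a difference by sex therefore cannot be told apart from one by group. Mitochondrial genes took 17.9% (GF replicate 1) to 35.3% (AF replicate 2) of the expected counts.

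**Figure D1:**
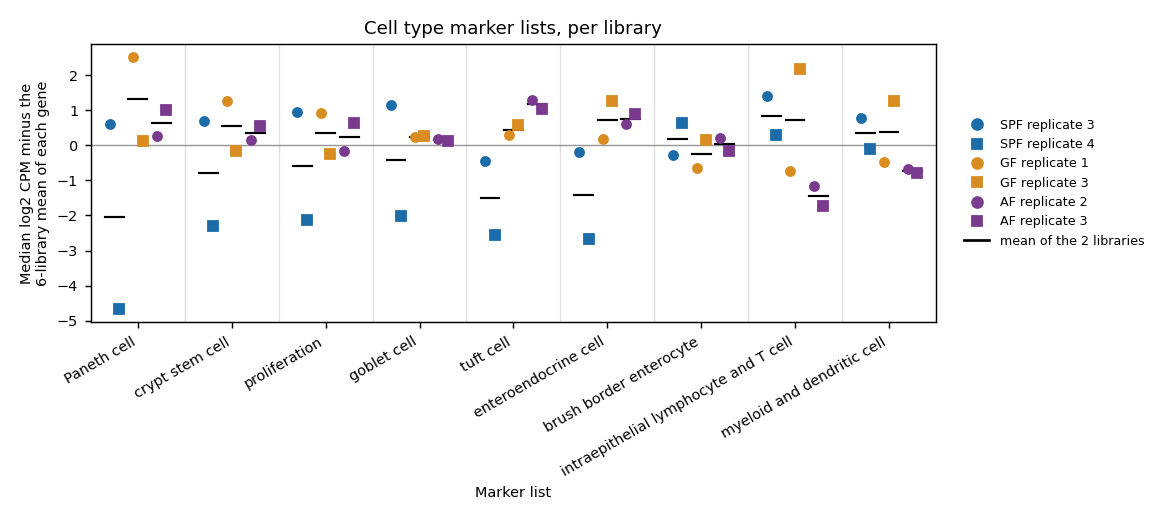
Cell type marker lists in each library. The y axis is the median over a list of log2 CPM minus each gene's mean over the 6 libraries, points are libraries, and bars are the means of the 2 libraries of a group. SPF replicate 4 lies at -4.68 for Paneth cells, and GF replicate 3 at 2.16 for intraepithelial lymphocytes and T cells.

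GF versus SPF asked what differed without a microbiota, though sex-linked transcripts differed between these groups as well. Reg3g, a secreted lectin that acts on Gram-positive bacteria (ENSMUSG00000030017, chromosome 6, 78466269 to 78468872), stood at 1131 ± 629.9 CPM in SPF and 227 ± 14.8 CPM in GF. The epithelial host defence list fell, and so did the interferon response list, with a median log2 fold change of -1.12 and 40 of its 42 tested genes lower. The tuft and enteroendocrine cell lists rose, with 0 members passing adjusted over the list alone, beside the low levels of the same markers in SPF replicate 4. With camera these list calls were lost at an adjusted p = 0.213 with an estimated correlation for host defence and an adjusted p = 0.729 with an estimated correlation for the other 3. With edgeR's quasi-likelihood test adjusted over all genes, only the Y-linked Eif2s3y and Kdm5d passed.

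In the epithelial host defence list, 18 of 23 tested genes were lower in GF and the list fell (median -0.67, camera adjusted p = 2.03e-06, adjusted p = 0.213 with an estimated correlation). 7 members were lower adjusted over the list alone, Reg3g, with a log2 fold change of -2.32 (SE 0.47), and Il18, an inflammasome cytokine (47.2 ± 4.32 CPM in SPF and 22.8 ± 3.17 CPM in GF), among them. Over all genes edgeR called 0 of the list, 9 were below an unadjusted p of 0.05, DESeq2 and edgeR's likelihood ratio test called 5 each, and limma on TPM called 0.

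In the interferon response list, camera gave an adjusted p of 1.39e-19, or adjusted p = 0.729 with an estimated correlation. 15 members were lower in GF adjusted over the list alone. Over all genes edgeR called 0, with 24 below an unadjusted p of 0.05, 6 called by DESeq2, 6 by the likelihood ratio test and 0 by limma. Ifi44, an interferon-induced gene, measured 13.4 ± 1.65 CPM in SPF and 2.17 ± 1.06 CPM in GF, a log2 fold change of -2.65 (SE 0.44). Trim30a measured 27.9 ± 7.17 and 8.77 ± 3.43 CPM. Without GF replicate 3 the list's median was -2.05. The GF libraries lay apart: the list's centred median log2 level was -0.98 in GF replicate 1 and 0.053 in GF replicate 3. In SPF replicates 3 and 4 it was 0.64 and 0.95.

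Genes of MHC class II presentation, which load and display peptides to CD4 T cells, were lower in GF as a list, and several differed more between the GF libraries than between the group means. Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), stood at 279 and 329 CPM in SPF but at 10.2 CPM in GF replicate 1 and 220.2 CPM in GF replicate 3. H2-Ab1, a class II chain (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), likewise measured 122 and 187 CPM against 13.1 and 124 CPM, and Ciita, the class II transactivator (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), 8.66 and 13.7 CPM against 1.97 and 7.67 CPM. The library with the higher class II levels, GF replicate 3, was also the one with the higher lymphocyte markers, Gzma measuring 137 against 12.9 CPM. The log2 fold changes of H2-Aa, H2-Eb1 and H2-DMa were -1.15 (SE 1.16), -1.08 (SE 0.99) and -0.81 (SE 0.69), and none passed edgeR's test (adjusted p = 0.848, 0.831 and 0.817). They were -0.21, -0.19 and -0.064 without GF replicate 1, and -4.72, -3.71 and -2.39 without GF replicate 3. The class II list as a whole fell, with 9 of 10 genes lower and a median of -1.11 (camera adjusted p = 6.92e-05, adjusted p = 0.729 with an estimated correlation), which was -0.37 without GF replicate 1 and -3.04 without GF replicate 3. No member passed adjusted over the list alone or over all genes by edgeR, DESeq2, the likelihood ratio test or limma, and 2 were below an unadjusted p of 0.05. The member with the smallest p was Lgmn, a lysosomal protease, at 17 ± 1.79 and 8.57 ± 0.16 CPM.

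**Figure D2:**
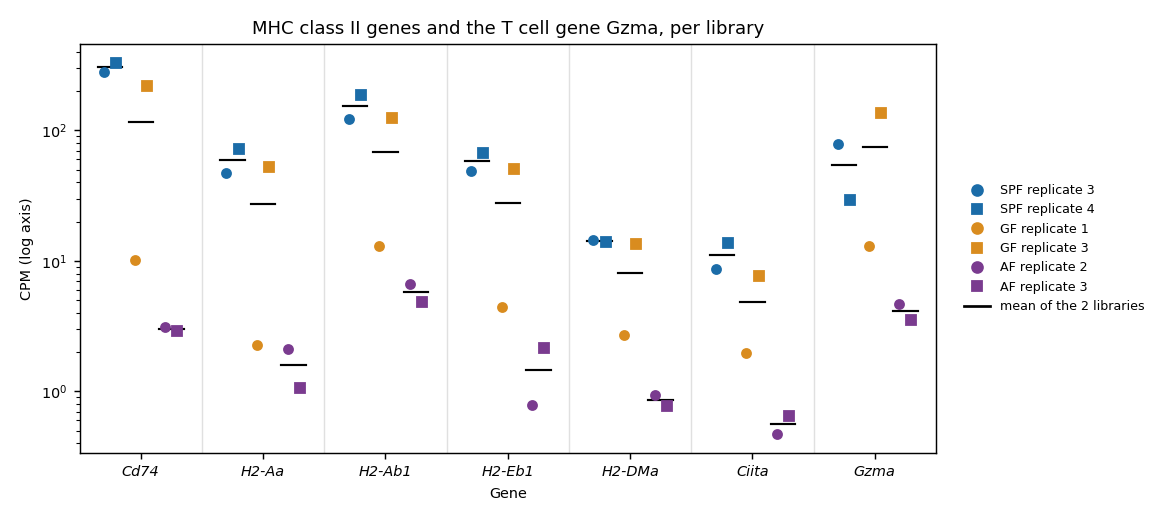
MHC class II genes and the T cell gene Gzma in each library, in CPM on a log axis, where points are libraries and bars the means of the 2 libraries of a group. Cd74 spans 10.2 to 220.2 CPM between the GF libraries and stays at 2.91 to 3.14 CPM in AF.

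The MHC class I presentation list fell in GF by less, with 25 of 30 genes lower and a median of -0.49 (camera adjusted p = 1.18e-05, adjusted p = 0.729 with an estimated correlation). B2m, the class I light chain, stood at 1008 ± 359.9 CPM in SPF and 623 ± 163 CPM in GF, H2-K1 at 1679 ± 621 and 1031 ± 428 CPM, Tap1, a peptide transporter subunit, at 160.5 ± 39.9 and 82.1 ± 36.4 CPM, and Psmb8, an immunoproteasome subunit, at 148 ± 27.4 and 102 ± 47.7 CPM. Nlrc5, the class I transactivator, measured 32 ± 11.5 and 7.95 ± 9.19 CPM, and H2-Q1 164 ± 81.1 and 73 ± 13.2 CPM. The genes of this family are similar to each other, and reads can have been split between them by the authors' counting. 0 members passed adjusted over the list alone or over all genes by edgeR or the other tools, and 3 were below an unadjusted p of 0.05. The median was -0.20 without GF replicate 1, -0.98 without GF replicate 3, -0.28 without SPF replicate 4 and -0.25 with a crypt marker score as a covariate, an alternative added after the data were seen.

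The lists of tuft, enteroendocrine and Paneth cell markers were higher by their medians in GF than in SPF, whose replicate 4 was low in these markers. In each of these lists 0 members passed adjusted over the list alone. The tuft cell list rose by a median of 1.68 (17 of 18 genes higher, camera adjusted p = 2.61e-08) and the enteroendocrine list by 1.71 (21 of 21, adjusted p = 8.98e-09), both with adjusted p = 0.729 with an estimated correlation. Dclk1, a tuft cell kinase, measured 1.85 ± 1.26 CPM in SPF and 6.09 ± 0.411 CPM in GF, and Scg5, of secretory granules, 2.39 ± 1.73 and 11.2 ± 6.16 CPM. Alox5ap measured 1.09 ± 0.859 and 5.37 ± 2.19 CPM, and Pcsk1n 2.92 ± 2.48 and 17 ± 13.7 CPM. Without SPF replicate 4 the tuft and enteroendocrine medians were 0.96 and 0.98, and without SPF replicate 3 they were 3.28 and 3.38. Without GF replicate 3 the enteroendocrine median was 1.01. The Paneth cell list rose by a median of 2.13 (camera adjusted p = 8.01e-06, adjusted p = 0.729 with an estimated correlation), which was 6.68 without SPF replicate 3, 0.38 without GF replicate 1, and 1.15 and no longer past the threshold without SPF replicate 4 (camera adjusted p = 0.126). With the crypt score as a covariate, of which this list is a part, it was 1.01. Guca2a, a guanylin of Paneth and goblet lists, measured 74.7 ± 17.8 and 154 ± 57.9 CPM.

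The crypt stem cell list (median 0.77, camera adjusted p = 0.0185) and the goblet cell list (0.19, adjusted p = 0.0319) passed with adjusted p = 0.757 and 0.863 with an estimated correlation, and both turned with single libraries. Their medians were -0.12 and -0.67 without SPF replicate 4, where the goblet list passed as lower in GF (camera adjusted p = 2.2e-09), -0.28 and -0.040 without GF replicate 1, and 3.33 and 2.36 without SPF replicate 3. Without GF replicate 3 the stem cell median was 1.34, and the goblet median, 0.18, no longer passed. The B cell and plasma cell list, of which only 3 genes were tested, passed at a median of -1.52 (camera adjusted p = 0.037, adjusted p = 0.729 with an estimated correlation) and lost the call whichever library was left out. Its medians were then 0.42 (without SPF replicate 3), -0.090 (SPF replicate 4), 0.29 (GF replicate 1), -2.41 (GF replicate 3), 0.32 (AF replicate 2) and 0.30 (AF replicate 3). With the crypt score as a covariate the stem cell and goblet lists no longer passed (medians -0.061 and -0.30).

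Lists of enterocyte genes of nutrient and drug handling fell in GF against SPF, whose replicate 4 was poor in crypt markers and stood at 0.64 for the brush border list against -0.28 in replicate 3. The 6 lists were proximal small intestine (median log2 fold change -0.73, camera adjusted p = 5.28e-06), xenobiotic metabolism (-0.68, 6.64e-05), fatty acid oxidation (-0.62, 2.45e-04), carbohydrate digestion (-0.57, 1.97e-04), lipid absorption (-0.56, 8.01e-06) and brush border enterocytes (-0.49, 0.00526). Camera gave adjusted p = 0.729 with an estimated correlation for the proximal, lipid and fatty acid lists, and adjusted p = 0.757 with an estimated correlation for the others. 0 of their members passed edgeR adjusted over the list alone or over all genes, and DESeq2, the likelihood ratio test and limma called 0 lower, while DESeq2 called 1 higher in the carbohydrate list and 1 in the fatty acid list, and the likelihood ratio test 1 higher in the fatty acid list. Cyp3a11, a drug-metabolising cytochrome, measured 332 and 1196 CPM in SPF replicates 3 and 4 and 197 ± 29.2 CPM in GF, and Fabp1, the liver-type fatty acid binding protein, 1495 and 2948 CPM and 909 ± 87.4 CPM. Slc40a1, the iron exporter, measured 109.6 ± 66.7 and 30.8 ± 8.35 CPM, Slc2a2, a glucose transporter, 289 ± 183 and 92.9 ± 8.87 CPM, and Ces2a 478 ± 299.9 and 159 ± 38.9 CPM. Members with higher values in GF included Pck1, of gluconeogenesis, at 119 ± 67.1 and 427 ± 67 CPM, and Angptl4, an inhibitor of lipoprotein lipase, at 41.1 ± 15.6 and 163 ± 60.9 CPM. Without SPF replicate 4 none of the 6 lists passed, with medians of -0.055 (proximal), 0.10 (xenobiotic), -0.19 (fatty acid), 0.019 (carbohydrate), -0.11 (lipid) and 0.10 (brush border). Without SPF replicate 3 the medians were -1.15, -1.12, -0.88, -0.99, -0.91 and -0.89. Without GF replicate 1 the carbohydrate median was -0.35 and the brush border list, at -0.14, no longer passed, and without GF replicate 3 the lipid and brush border medians were -0.86 and -0.90. With the crypt score as a covariate the proximal list still passed (median -0.18), and the other 5 did not, at -0.070 (xenobiotic), -0.25 (fatty acid), -0.062 (carbohydrate), -0.16 (lipid) and 0.092 (brush border).

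Cholesterol biosynthesis rose by a median of 0.58 (camera adjusted p = 1.92e-04, adjusted p = 0.729 with an estimated correlation). It was 0.35 without SPF replicate 4, 0.29 with the crypt score as a covariate, 0.88 without GF replicate 3, and 0.24 and not past the threshold without GF replicate 1. The distal small intestine list rose by 0.46 (camera adjusted p = 0.0222, adjusted p = 0.729 with an estimated correlation) and lost the call without SPF replicate 3 or GF replicate 1 (medians 0.45 and 0.31) and with library totals alone (0.64). 5 of its 19 genes were higher adjusted over the list alone. Fgf15, the bile acid-induced hormone of the ileum, measured 2.55 ± 1.18 and 15.5 ± 5.96 CPM and was the 1 gene of the bile acid list to pass in this way. Mep1a, a meprin protease in the same distal list, measured 111 ± 13.2 and 218 ± 36.9 CPM.

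The circadian clock genes split into members higher and members lower in GF. 8 of the 18 tested were higher and 8 lower adjusted over the list alone, while edgeR called 0 over all genes (8 higher and 8 lower below an unadjusted p of 0.05, 5 and 1 by DESeq2, 5 and 2 by the likelihood ratio test, 0 by limma). Nr1d1, the repressor REV-ERB alpha (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), measured 12 ± 6.91 CPM in SPF and 72.7 ± 5.86 CPM in GF, a log2 fold change of 2.61 (SE 0.43), and Tef 5.56 ± 0.673 and 18.2 ± 0.205 CPM. The list as a whole did not pass camera (adjusted p = 0.956), and its median of -0.48, mean of 0.27 and downward test differ in sign.

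**Figure D3:**
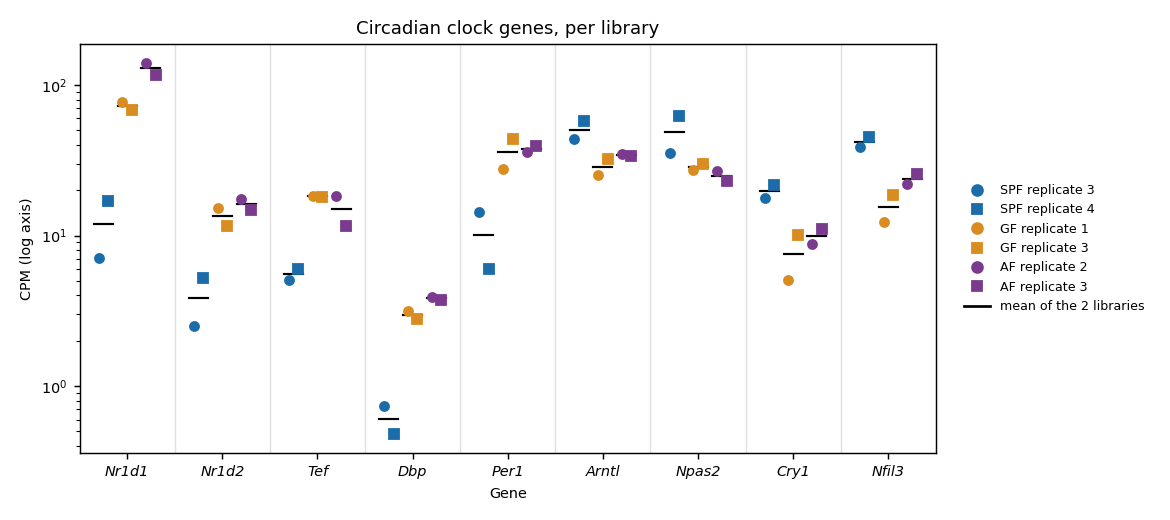
Circadian clock genes in each library, in CPM on a log axis, where points are libraries and bars the means of the 2 libraries of a group. Apart from Nr1d1 and Tef the genes plotted were chosen after their values were seen. Nr1d1 lies at 7.1 and 16.9 CPM in SPF and at 68.6 to 140.1 CPM in the GF and AF libraries.

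Of 13644 genes, edgeR called 2 in GF versus SPF, both higher. Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) and Kdm5d (ENSMUSG00000056673, chromosome Y, 897788 to 956786) had 0 counts in SPF and 23.1 ± 0.979 and 18.1 ± 0.223 CPM in GF, at least 284-fold and 219.9-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.0239 for both). The Y-linked Ddx3y and Uty, at least 135-fold and 70.2-fold higher, did not pass edgeR's test over all genes (adjusted p = 0.107 and 0.521). The next gene named by its p was the autosomal histone gene Hist1h2bk, at 0.0458 ± 0.0648 CPM in SPF and 3.05 ± 0.478 CPM in GF (edgeR adjusted p = 0.738), a ratio of 57.4 with an exact 95% counting interval of 15.6 to 479 on 2 counts in SPF, which leaves out the uncertainty of its shared reads. All 5 genes of the sex-linked list passed adjusted over the list alone, Xist being lower, and this list's camera adjusted p was 2.41e-09, or adjusted p = 0.213 with an estimated correlation. Leaving out the sex-linked genes, edgeR called 0. Of all genes, 916 were below an unadjusted p of 0.05 (437 higher and 479 lower). With sex-linked genes kept, DESeq2 called 80, edgeR's likelihood ratio test 97 and limma on TPM 5, of which 4, 4 and 1 were sex-linked. Kdm5d missed the threshold with limma (adjusted p = 0.323). The count of 2 became 369 without SPF replicate 3 and 0 without GF replicate 1, GF replicate 3, AF replicate 2 or AF replicate 3, and also 0 with library totals alone or with only the 2 groups in the fit. 19 of 30 lists passed camera (8 rose, 11 fell), 12 of 30 without SPF replicate 4, and 0 of 30 with an estimated correlation.

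Lists that did not pass camera in GF versus SPF were proliferation (median 0.25, adjusted p = 0.0715), amino acid stress response (0.22, 0.231), intraepithelial lymphocytes and T cells (0.31, 0.311), dissociation stress (-0.092, 0.665), myeloid and dendritic cells (0.19, 0.705), peptide and amino acid absorption (-0.0091, 0.789), aryl hydrocarbon receptor targets (-0.39, 0.79), retinoid metabolism (-0.10, 0.79), bile acid handling (-0.29, 0.899) and stromal and endothelial cells (0.35, 0.956). The T cell and myeloid lists had a median and mean above 0 and a downward test, and the aryl hydrocarbon receptor, retinoid, bile acid and dissociation lists a mean above 0 with a median below 0 and a downward test.

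AF versus GF asked what differed when food antigens were removed as well, together with any other difference between the diets. The homeobox factor Isx, a repressor of intestinal vitamin A uptake (ENSMUSG00000031621, chromosome 8, 74873173 to 74893506), fell from 81.6 ± 0.573 CPM in GF to 1.08 ± 0.356 CPM in AF. Its known targets had higher levels in AF: Bco1, the enzyme that splits beta-carotene (ENSMUSG00000031845, chromosome 8, 117095854 to 117133720), stood at 14 ± 10.7 CPM in GF and 1025 ± 176 CPM in AF, and Scarb1, a carotenoid and lipid receptor (ENSMUSG00000037936, chromosome 5, 125277087 to 125341094), at 11.4 ± 6.8 and 644 ± 122 CPM. The MHC class II, T cell, peptide and amino acid absorption and xenobiotic metabolism lists fell in AF. With camera these calls were lost, at an adjusted p = 0.658 with an estimated correlation for xenobiotic metabolism and an adjusted p = 0.608 with an estimated correlation for the other 3.

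2 genes passed edgeR's test over all genes. Isx had a log2 fold change of -6.25 (SE 0.34) and an edgeR adjusted p of 0.0186. Pkd1l2, a polycystin family gene (ENSMUSG00000034416, chromosome 8, 116995679 to 117082449), rose from 0.0522 ± 0.0222 CPM, 2 counts over both GF libraries, to 31.7 ± 4.88 CPM (edgeR adjusted p = 0.0299), a ratio of 659 with an exact 95% counting interval of 182 to 5450.1. Pkd1l2 lies 13404 bases from Bco1 on the opposite strand, the genes pointing away from each other. Bco1 and Scarb1, with log2 fold changes of 6.20 (SE 0.82) and 5.83 (SE 0.79), did not pass over all genes (edgeR adjusted p = 0.563 and 0.563). Apart from fits with a library left out, each passed over all genes under 6 of 13 alternatives and missed the threshold under the others. The crypt score covariate, added after the data were seen, was among the 6. Both passed adjusted over their own lists alone, retinoid metabolism and lipid absorption (edgeR adjusted p = 0.00177 and 0.00925). Cd36, a fatty acid translocase, measured 34.2 ± 2.63 and 9.4 ± 2.37 CPM. Neither list passed camera (medians -0.16 and 0.014, adjusted p = 0.618 and 0.246).

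**Figure D4:**
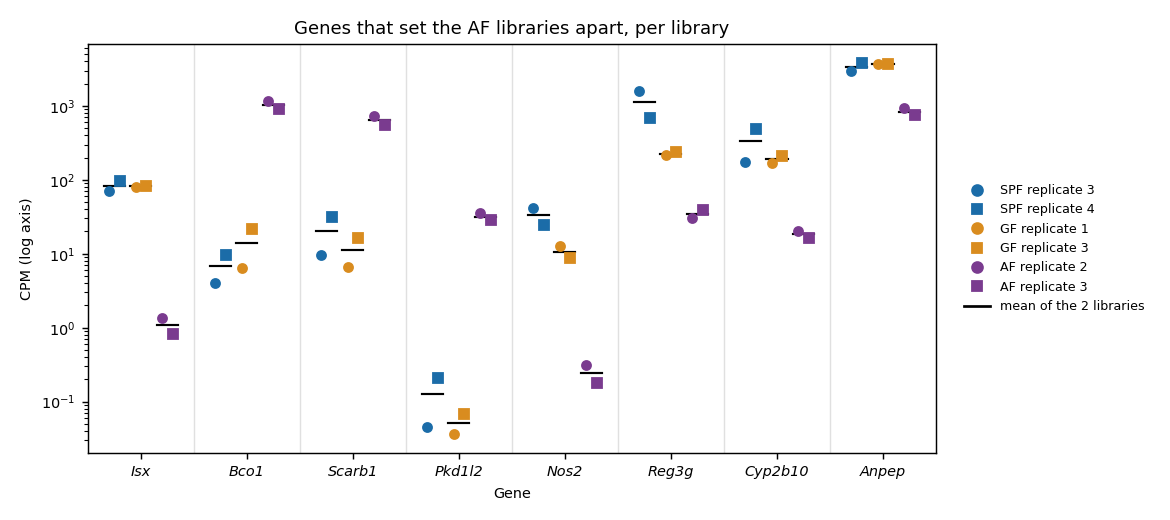
Genes that set the AF libraries apart, in CPM on a log axis, where points are libraries and bars the means of the 2 libraries of a group. Isx lies at 0.832 and 1.34 CPM in AF and at 71.4 to 94.9 CPM in the other libraries, and Bco1 at 899.9 and 1149 CPM in AF and at 3.98 to 21.6 CPM elsewhere.

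In the MHC class II list, 8 of 10 genes were lower in AF and the list fell (median -3.40, camera adjusted p = 9.53e-06, adjusted p = 0.608 with an estimated correlation). 7 members were lower adjusted over the list alone. Across all genes, edgeR called 0, with 7 below an unadjusted p of 0.05, 7 called by DESeq2, 4 by the likelihood ratio test and 0 by limma. Cd74 measured 3.14 and 2.91 CPM in AF replicates 2 and 3 against 10.2 and 220.2 CPM in GF replicates 1 and 3, a log2 fold change of -5.25 (SE 1.37), which was -1.75 without GF replicate 3. H2-Aa stood at 2.26 and 52 CPM in GF and 1.6 ± 0.743 CPM in AF, H2-Ab1 at 13.1 and 124 CPM and 5.73 ± 1.22 CPM, and H2-Eb1 at 4.45 and 51 CPM and 1.46 ± 0.957 CPM. Ciita and H2-DMa, with log2 fold changes of -3.05 (SE 0.76) and -3.23 (SE 0.80), had the smallest p of the list, and without GF replicate 3 these values were -1.78 and -1.65. Without GF replicate 3, the library rich in lymphocyte markers, the list's median was -1.38. This value rests on GF replicate 1 alone for GF. That library also had a higher summed T cell list, 55.1 CPM, than AF replicates 2 and 3, at 34.1 and 23.1 CPM.

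The MHC class I list fell by less, with 26 of 30 genes lower and a median of -0.34 (camera adjusted p = 0.0474, adjusted p = 0.906 with an estimated correlation). It did not pass with median-of-ratios scaling (camera adjusted p = 0.0531) or without AF replicate 3 (median -0.24), its median was -0.57 without GF replicate 1, and it turned to 0.083 without GF replicate 3. H2-Q10 was higher, at 7.33 ± 0.77 CPM in GF and 27 ± 3.18 CPM in AF, and was the 1 member to pass adjusted over the list alone. The sign of several members turned without GF replicate 3, where the log2 fold changes of H2-K1, Tap1, Psmb8 and Nlrc5 were 0.44, 0.084, 0.18 and 1.83 in place of -0.062 (SE 0.48), -0.46 (SE 0.39), -0.40 (SE 0.37) and -0.59 (SE 0.95). H2-K1 was at 0.10 without AF replicate 3. B2m measured 623 ± 163 and 488 ± 68.9 CPM.

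Markers of intraepithelial lymphocytes and T cells fell in AF, with all 31 tested genes lower and a median of -3.08 (camera adjusted p = 7.0e-15, adjusted p = 0.608 with an estimated correlation). The median was -2.99 with the 1 gene at 0 counts in AF set at its bound, and -0.71 without GF replicate 3. Gzma, granzyme A of cytotoxic lymphocytes, measured 12.9 and 137 CPM in GF and 4.11 ± 0.853 CPM in AF, and Coro1a 2.41 and 12.3 CPM and 0.642 ± 0.353 CPM. The myeloid and dendritic cell list fell, with a median log2 fold change of -1.51 over 9 genes (camera adjusted p = 0.00458, adjusted p = 0.608 with an estimated correlation) and lost the call without GF replicate 3 (median -0.37) or AF replicate 3 (-1.76). 0 members of either list passed adjusted over the list alone. Over all genes edgeR called 0 T cell genes, with 19 below an unadjusted p of 0.05, 3 called by DESeq2, 2 by the likelihood ratio test and 0 by limma, and of the myeloid genes 0 by each measure.

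Host defence genes fell again, with a list median of -0.74 (camera adjusted p = 9.53e-06, adjusted p = 0.5 with an estimated correlation). Adjusted over the list alone, 3 members, Nos2, Reg3g and Duox2, were lower and 1, Il18, was higher. Il18 had been lower in GF than in SPF. Nos2, inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), measured 10.6 ± 2.68 CPM in GF and 0.246 ± 0.0961 CPM in AF (edgeR adjusted p = 0.152 over all genes), and Reg3g 227 ± 14.8 and 34.7 ± 5.36 CPM. The median was -0.49 without GF replicate 1. Interferon genes did not pass as a list (median -0.00026, mean -0.21, an upward test with a camera adjusted p of 0.291). Oas2 measured 26.8 ± 17 and 77 ± 14.9 CPM, and Ifit3 17.6 ± 6.74 and 38 ± 5.25 CPM.

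Peptide and amino acid absorption fell in AF, with 26 of 30 genes lower and a median of -0.63 (camera adjusted p = 3.79e-10, adjusted p = 0.608 with an estimated correlation). Anpep, the brush border aminopeptidase N, measured 3674 ± 4.06 CPM in GF and 836 ± 125 CPM in AF, a log2 fold change of -2.14 (SE 0.44), and Mep1a 218 ± 36.9 and 90 ± 18.7 CPM. 0 members passed adjusted over the list alone or over all genes by edgeR, where 9 were lower and 1 higher below an unadjusted p of 0.05 and DESeq2 called 3, the likelihood ratio test 1 and limma 0. Xenobiotic metabolism fell, with a median log2 fold change of -0.59, -0.39 without GF replicate 1 (camera adjusted p = 3.18e-08, adjusted p = 0.658 with an estimated correlation). Its 2 members lower adjusted over the list alone were Cyp2b10, a target of the nuclear receptor CAR (188 ± 26.8 and 18.4 ± 3.08 CPM), and the carboxylesterase Ces1f (98.1 ± 30.4 and 9.17 ± 0.362 CPM). Targets of the aryl hydrocarbon receptor, which senses dietary and microbial indoles, fell, with a median log2 fold change of -1.63 over 7 genes (camera adjusted p = 7.57e-04, adjusted p = 0.608 with an estimated correlation), -0.93 with a filter of 1 CPM in 2 libraries. Cyp1a1 measured 32.2 ± 3.48 and 4.59 ± 2.5 CPM, and Nqo1 15 ± 5.48 and 4.86 ± 0.57 CPM. 3 of them were lower adjusted over the list alone.

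The tuft cell list rose further, by a median of 0.76 with all 18 genes higher (camera adjusted p = 2.1e-04, adjusted p = 0.658 with an estimated correlation), and by 0.47 without GF replicate 1. Avil, an actin-binding tuft cell gene, measured 22.5 ± 4.05 and 40.9 ± 5.24 CPM. Small list changes that single libraries ended were those of carbohydrate digestion (median 0.34, camera adjusted p = 0.0026, adjusted p = 0.854 with an estimated correlation), cholesterol biosynthesis (-0.27, 0.00698 and 0.854), the distal list (-0.38, 0.00427 and 0.608), the clock (0.27, 0.0197 and 0.608) and dissociation stress (0.25, 0.00341 and 0.608). Without GF replicate 1 none of these passed, the medians being 0.39, 0.095, -0.21, 0.16 and 0.16. Without AF replicate 2 the carbohydrate (0.50), cholesterol (-0.13) and clock (0.19) lists lost the call, the distal and dissociation medians being -0.58 and 0.40. Without AF replicate 3 the distal (-0.29) and dissociation (0.12) lists lost it, the cholesterol median being -0.64. Without GF replicate 3 the cholesterol, distal and clock medians were -0.54, -0.22 and 0.42. With library totals alone, which moved the median of all genes to -0.379, the carbohydrate, clock and dissociation medians turned to -0.00793, -0.076 and -0.063, and the cholesterol list, at -0.65, did not pass. Sis, sucrase-isomaltase, measured 1008 ± 70.8 and 1967 ± 86.2 CPM, the fructokinase Khk 252 ± 26.7 and 508 ± 14.4 CPM, and Pck1 427 ± 67 and 91.8 ± 29.7 CPM.

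Camera did not pass, in AF versus GF, bile acid handling (median -0.36, adjusted p = 0.0576), B cells and plasma cells (-1.98, 0.078), brush border enterocytes (0.23, 0.143), the proximal list (0.23, 0.297), stromal and endothelial cells (-0.63, 0.301), Paneth cells (-0.87, 0.374), goblet cells (-0.15, 0.537), crypt stem cells (-0.32, 0.557), amino acid stress (0.0074, 0.557), the sex-linked list (-0.042, 0.643), proliferation (-0.067, 0.798), enteroendocrine cells (-0.10, 0.81) or fatty acid oxidation (-0.033, 0.879). In the last, Angptl4 measured 163 ± 60.9 and 41.3 ± 11.9 CPM and was past the threshold adjusted over the list alone. Median or mean and test direction differed in sign for interferon response, fatty acid oxidation, amino acid stress, proliferation and enteroendocrine cells.

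edgeR called 2 of 13644 genes in AF versus GF, 1 higher and 1 lower, with 491 below an unadjusted p of 0.05 (208 higher, 283 lower). These 491 were 3.6% of the genes tested, less than a threshold of 0.05 would give if no gene differed. The shares were 6.71% in GF versus SPF and 11.3% in AF versus SPF. DESeq2 called 51, the likelihood ratio test 53 and limma on TPM 9, without Pkd1l2 (limma adjusted p = 0.0821), and library totals alone gave 4 (3 higher and 1 lower). The count was 9 without SPF replicate 3, 7 without SPF replicate 4 and 0 without GF replicate 1, GF replicate 3, AF replicate 2 or AF replicate 3, where Isx had edgeR adjusted p values up to 0.442 and Pkd1l2 up to 0.69. With effective lengths as offsets it was 1, Pkd1l2 no longer passing edgeR's test (adjusted p = 0.125), and with only the 2 groups in the fit it was 8. 14 of 30 lists passed camera (4 rose, 10 fell), and 0 with an estimated correlation.

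AF versus SPF took the microbiota, food antigens and any other difference of diet together, and sex-linked transcripts differed between these groups as well. Nos2 fell from 33.3 ± 12.4 CPM in SPF to 0.246 ± 0.0961 CPM in AF, and Isx from 83.2 ± 16.6 to 1.08 ± 0.356 CPM. Cd74 stood at 304 ± 35.4 CPM in SPF and 3.03 ± 0.163 CPM in AF, with both AF libraries below both SPF libraries, and the MHC class II list fell, with a median log2 fold change of -4.52. Interferon, host defence, xenobiotic and T cell lists fell, and the tuft cell list rose, beside the low tuft cell markers of SPF replicate 4. With camera all 6 calls were lost with an estimated correlation, at an adjusted p = 0.565 for class II, interferon and tuft cells, 0.597 for xenobiotic metabolism and T cells, and 0.175 for host defence.

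6 of 13644 genes passed edgeR's test, 4 higher and 2 lower. Nos2 had a log2 fold change of -7.08 (SE 0.51) and Isx of -6.27 (SE 0.34), with edgeR adjusted p = 0.0222 and 0.0156. Pkd1l2 measured 0.126 ± 0.113 CPM in SPF and 31.7 ± 4.88 CPM in AF, a ratio of 285 with an exact 95% counting interval of 111 to 1047 (edgeR adjusted p = 0.0203). The other 3 were the Y-linked Eif2s3y, Kdm5d and Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), at least 270.2-fold, 200-fold and 145-fold higher, and the sex-linked list passed camera (adjusted p = 1.19e-07, adjusted p = 0.175 with an estimated correlation). Bco1 (6.79 ± 3.97 and 1025 ± 176 CPM) and Scarb1 (20.3 ± 15.1 and 644 ± 122 CPM) had log2 fold changes of 7.24 (SE 0.86) and 4.99 (SE 0.76) and did not pass edgeR's test over all genes (adjusted p = 0.163 and 0.259), while both passed adjusted over their lists alone. Cd36 measured 28.8 ± 9.35 and 9.4 ± 2.37 CPM. 1540 genes were below an unadjusted p of 0.05 (650 higher, 890 lower), DESeq2 called 272 and the likelihood ratio test 298. The count of 6 was 625 without SPF replicate 3, 13 without SPF replicate 4, 2 without GF replicate 1 or GF replicate 3, 0 without AF replicate 2 or AF replicate 3, and 2 with only the 2 groups in the fit. None of the 6 named genes passed without a GF or an AF library or with only the 2 groups in the fit, the highest edgeR adjusted p being 0.265 for Isx, 0.405 for Nos2 and 0.405 for Pkd1l2. With library totals alone edgeR lost Nos2 (adjusted p = 0.0889) and Ddx3y (0.112), with effective lengths Pkd1l2 and Ddx3y (adjusted p = 0.098 for both), and limma on TPM lost Nos2 (adjusted p = 0.169), Pkd1l2 (0.0851), Kdm5d (0.229) and Ddx3y (0.278).

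In the MHC class II list 9 of 10 genes were lower in AF (camera adjusted p = 2.06e-08, adjusted p = 0.565 with an estimated correlation), 8 of them adjusted over the list alone. Over all genes edgeR called 0, with 9 below an unadjusted p of 0.05, 7 called by DESeq2, 7 by the likelihood ratio test and 0 by limma. The log2 fold change was -6.65 (SE 1.46) for Cd74, -4.76 (SE 1.06) for H2-Ab1, -5.25 (SE 1.44) for H2-Aa, -5.27 (SE 1.23) for H2-Eb1, -4.04 (SE 0.81) for H2-DMa and -4.28 (SE 0.78) for Ciita. The class I list fell, with a median log2 fold change of -0.75, with 27 of 30 genes lower (camera adjusted p = 5.2e-07, adjusted p = 0.565 with an estimated correlation). B2m had a log2 fold change of -1.05 (SE 0.41), H2-K1 of -0.77 (SE 0.48), Tap1 of -1.42 (SE 0.40), Psmb8 of -0.95 (SE 0.37), Psmb9 of -1.30 (SE 0.32) and Nlrc5 of -2.62 (SE 0.97). Those of B2m and H2-K1 were -0.63 and -0.33 without SPF replicate 4, and -0.69 and -0.35 with the crypt score as a covariate. H2-Q10, at 9.77 ± 1.12 and 27 ± 3.18 CPM, was again the 1 class I member past the threshold adjusted over the list alone, and it was higher. Over all genes edgeR called 0 class I members, with 11 lower and 1 higher below an unadjusted p of 0.05, 2 lower and 1 higher by DESeq2, 3 lower and 1 higher by the likelihood ratio test, and 0 by limma.

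All 42 tested interferon response genes were lower in AF than in SPF (median -1.12, camera adjusted p = 1.67e-13, adjusted p = 0.565 with an estimated correlation), 12 of them adjusted over the list alone. None passed edgeR over all genes, with 19 below an unadjusted p of 0.05, 10 called by DESeq2, 10 by the likelihood ratio test and 0 by limma. Irgm2, an interferon-gamma-induced GTPase, measured 42.4 ± 11.6 and 8.75 ± 2.29 CPM, and Ifi44 13.4 ± 1.65 and 3.03 ± 0.507 CPM. The host defence list fell, with a median log2 fold change of -1.13 (camera adjusted p = 5.24e-09, adjusted p = 0.175 with an estimated correlation), 10 members being lower adjusted over the list alone and 1, Nos2, over all genes. Reg3g measured 1131 ± 629.9 and 34.7 ± 5.36 CPM. T cell markers fell, with a median log2 fold change of -2.63, all 31 genes being lower (camera adjusted p = 7.69e-11, adjusted p = 0.597 with an estimated correlation), and Gzma measured 53.9 ± 34.5 and 4.11 ± 0.853 CPM. 0 of these genes passed edgeR adjusted over the list alone or over all genes, with 11 below an unadjusted p of 0.05, 4 called by DESeq2, 3 by the likelihood ratio test and 0 by limma. The interferon and host defence medians stayed at these values with their 1 gene each at 0 counts in a group set at its bound, and the T cell median was -2.56 in the same way. The myeloid list (-1.25, camera adjusted p = 0.00625) and the B cell list (-3.50, adjusted p = 0.00625) fell too, with adjusted p = 0.565 with an estimated correlation for both. Igkc, the kappa light chain, had 57 counts over both SPF libraries and 1 over both AF libraries, a ratio of 46.3 with an exact 95% counting interval of 7.98 to 1859. Without SPF replicate 3 neither list passed (medians -0.81 and -0.83), and the B cell median was -1.76 without SPF replicate 4 and -0.85, not past the threshold, without AF replicate 2.

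Xenobiotic metabolism fell, with a median log2 fold change of -1.04, 16 of 40 genes being lower adjusted over the list alone (camera adjusted p = 1.03e-11, adjusted p = 0.597 with an estimated correlation), and edgeR called 0 over all genes against 21 lower and 1 higher below an unadjusted p of 0.05, 13 by DESeq2, 10 by the likelihood ratio test and 2 by limma. Cyp2b10 measured 335 ± 224 and 18.4 ± 3.08 CPM, and Ces1f 139 ± 91.6 and 9.17 ± 0.362 CPM. The median was -0.44 without SPF replicate 4 and -0.69 with the crypt score as a covariate. Peptide absorption fell, with a median of -0.65, 6 members being lower adjusted over the list alone (camera adjusted p = 1.36e-06, adjusted p = 0.565 with an estimated correlation), -1.01 without SPF replicate 3, -0.33 without SPF replicate 4 and -0.33 with the crypt score as a covariate. Anpep measured 3399 ± 578 and 836 ± 125 CPM, and Slc36a1, a proton-coupled amino acid transporter, 134 ± 49.5 and 46.9 ± 5.94 CPM. Aryl hydrocarbon receptor targets fell, with a median of -1.36 (camera adjusted p = 0.00264, adjusted p = 0.565 with an estimated correlation), -0.58 without SPF replicate 4 and -0.83 with the crypt score as a covariate, with Nqo1 at 21.1 ± 8.0 and 4.86 ± 0.57 CPM. The proximal list (-0.55, camera adjusted p = 0.00216), fatty acid oxidation (-0.31, 0.00612) and lipid absorption (-0.43, 0.0111) also fell, with adjusted p = 0.658, 0.658 and 0.721 with an estimated correlation. Without SPF replicate 4 none of the 3 passed (medians -0.059, -0.026 and -0.00446), without SPF replicate 3 they were -1.05, -0.71 and -0.76, and without AF replicate 3 fatty acid oxidation (-0.23) and lipid absorption (-0.27) lost the call. The fatty acid oxidation median was -0.48 without AF replicate 2. With the crypt score as a covariate the 3 lists did not pass either, with medians of -0.18, -0.13 and 0.00778. Mme, a brush border endopeptidase, measured 486 ± 327 and 158 ± 13.7 CPM, and Fabp1 2222 ± 1028 and 807 ± 183 CPM.

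The tuft cell list rose by a median of 2.56, 11 of 18 genes being higher adjusted over the list alone (camera adjusted p = 5.23e-11, adjusted p = 0.565 with an estimated correlation), and edgeR called 0 over all genes against 14 below an unadjusted p of 0.05, 7 by DESeq2, 6 by the likelihood ratio test and 0 by limma. It was 1.69 without SPF replicate 4 and 4.08 without SPF replicate 3. Dclk1 measured 1.85 ± 1.26 and 8.84 ± 0.155 CPM, and Alox5ap 1.09 ± 0.859 and 8.19 ± 1.41 CPM. The enteroendocrine list rose by 1.63 (camera adjusted p = 1.19e-07, adjusted p = 0.597 with an estimated correlation), 0.88 without SPF replicate 4 and 3.07 without SPF replicate 3. Sst, somatostatin, measured 50.1 and 3.43 CPM in SPF and 307 ± 112 CPM in AF, and Scg5 2.39 ± 1.73 and 10.1 ± 1.37 CPM. The Paneth list rose by 1.03 (camera adjusted p = 7.75e-04, adjusted p = 0.658 with an estimated correlation), 5.71 without SPF replicate 3, 0.42 without AF replicate 3, and 0.25 and not past the threshold without SPF replicate 4. The clock list did not pass (median -0.14, mean 0.54, an upward test with a camera adjusted p of 0.382), with 7 members higher and 5 lower adjusted over the list alone. Nr1d1 measured 12 ± 6.91 and 129 ± 16.2 CPM, and the ubiquitin protease Usp2 32.6 ± 9.38 and 12 ± 0.0459 CPM. Fgf15 (2.55 ± 1.18 and 17.1 ± 6.9 CPM) and the bile salt exporter Abcc3 (137 ± 52.1 and 40.5 ± 5.11 CPM) both passed adjusted over the bile acid list alone.

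17 of 30 lists passed camera in AF versus SPF (4 rose, 13 fell), and 0 with an estimated correlation. The lists that did not pass, besides the clock, were proliferation (median 0.20, adjusted p = 0.0678), amino acid stress (0.30, 0.101), crypt stem cells (0.47, 0.101), dissociation stress (0.093, 0.133), goblet cells (-0.19, 0.176), brush border enterocytes (-0.29, 0.176), bile acid handling (-0.53, 0.176), cholesterol biosynthesis (0.30, 0.176), carbohydrate digestion (-0.078, 0.322), stromal and endothelial cells (-0.39, 0.371), retinoid metabolism (-0.025, 0.456) and the distal list (-0.043, 0.916). Test and median or mean differed in sign for the clock, goblet and distal lists.

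A test for any difference among the 3 groups called 4 genes with edgeR, Pkd1l2 and Isx (adjusted p = 0.0246 for both), Eif2s3y (0.0269) and Kdm5d (0.0321), with 1000 below an unadjusted p of 0.05. The count was 207 with DESeq2, 136 without SPF replicate 3 and 0 without GF replicate 1, GF replicate 3, AF replicate 2 or AF replicate 3. Across the 13644 genes, which are not independent replicates, the log2 fold changes of GF versus SPF and AF versus SPF correlated with Pearson's r = 0.685, and r ranged from 0.492 without GF replicate 1 to 0.887 without SPF replicate 3. Both comparisons share the SPF libraries. On log2(CPM + 0.5) means r was 0.754 and the covariance 0.327. Over 100 simulations set against the same SPF libraries the means were 0.582 and 0.177, and the highest values 0.596 and 0.184. The simulated GF and AF libraries were drawn around the mean of all libraries, GF and AF among them. The simulated values thus hold part of any real difference from SPF that GF and AF share. The covariances differed by 0.15, which is not the excess over the shared SPF libraries alone. The 2 genes called higher in both comparisons, Eif2s3y and Kdm5d, are Y-linked and had 0 counts in the SPF libraries that both comparisons use, and 0 were called lower in both. Independent lists would share 5.86e-04 higher and 0 lower genes, values that leave out the shared SPF libraries. The SPF libraries were not split, since each part would hold 1 library, and part of these values can come from the sharing.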

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

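The crypt score covariate was chosen only after the data were seen, and the other alternatives before the data were examined. Of the list medians under alternatives, apart from the MHC lists, 382 kept their direction and their side of the threshold, 125 kept the direction but missed it and 19 turned, and of the values of single genes 1870 stayed, 267 passed where they had not, 61 no longer passed and 5 turned. Counts of called genes moved most. Against 2 in GF versus SPF, 2 in AF versus GF, 6 in AF versus SPF and 4 for any difference, no low-count filter gave 484, 264, 804 and 937, where genes at a few counts enter the test. DESeq2 gave 80, 51, 272 and 207, the likelihood ratio test 97, 53 and 298 in the 3 comparisons, and limma 5 and 9 in the first 2. Library totals alone gave 0 in GF versus SPF and 4 in AF versus GF, effective lengths 1 in AF versus GF, and only the 2 groups compared 0, 8 and 2. The crypt score covariate gave 23 in AF versus GF, 61 in AF versus SPF and 33 for any difference. With single libraries left out the counts ranged from 0 to 369 (GF versus SPF, highest without SPF replicate 3), 0 to 9 (AF versus GF, without SPF replicate 3), 0 to 625 (AF versus SPF, without SPF replicate 3) and 0 to 136 (any difference, without SPF replicate 3). Leaving out SPF replicate 3 leaves SPF replicate 4, poor in crypt markers, to stand for SPF. Camera with an estimated correlation called 0, 0 and 0 lists against 19, 14 and 17, and fry 1, 0 and 2, and the lists called in GF versus SPF ranged from 12 (without SPF replicate 4) to 21 with libraries left out. Under both of these tests the MHC class II medians of -1.11 (GF versus SPF), -3.40 (AF versus GF) and -4.52 (AF versus SPF) and the class I medians of -0.49, -0.34 and -0.75 missed the threshold, and class I in AF versus GF, -0.34 with median-of-ratios scaling, missed it there too. With libraries left out its median ranged over -0.57 to 0.083, the last without GF replicate 3. Lists that turned in GF versus SPF ranged, with libraries left out, over -0.99 to 0.019 (carbohydrate), -1.12 to 0.10 (xenobiotic), -0.28 to 3.33 (stem cell), -0.67 to 2.36 (goblet), -0.90 to 0.10 (brush border) and -2.41 to 0.42 (B cell), and cholesterol in AF versus GF over -0.64 to 0.095. The crypt score covariate turned the stem cell (-0.061), goblet (-0.30) and brush border (0.0919) medians of GF versus SPF and the lipid median of AF versus SPF (0.00778), and library totals alone the carbohydrate (-0.00793), clock (-0.076) and dissociation (-0.063) medians of AF versus GF, a scaling under which the median of all genes was 0.158 (GF versus SPF), -0.379 (AF versus GF) and -0.205 (AF versus SPF), against 0.0218, -0.0226 and 0.0115 with TMM. In AF versus GF the log2 fold changes of H2-K1 (-0.43 to 0.44), Tap1 (-0.85 to 0.084), Psmb8 (-0.81 to 0.18) and Nlrc5 (-1.47 to 1.83) crossed 0 with libraries left out. The correlation of the comparisons against SPF was 0.714 with a filter of 1 CPM in 2 libraries and ranged from 0.492 to 0.887 with libraries left out. The cause was not tested for these changes, apart from the smaller number of samples with a library left out. No paired analysis was possible because any 2 groups share only replicate number 3. Depth limits genes below the floor of 0.109 to 0.236 CPM.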

Other observations

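All 7 tests of explanations given here were chosen only after the result was seen. Further genes set the AF libraries apart, among them Aldh1a1, a retinal dehydrogenase that makes retinoic acid, at 229 ± 148 CPM in SPF, 184 ± 81.7 CPM in GF and 44.1 ± 4.92 CPM in AF, lower in AF versus GF adjusted over the retinoid list alone (edgeR adjusted p = 0.0444). Abca1, a cholesterol exporter, measured 9.03 ± 1.42, 5.93 ± 0.997 and 15.6 ± 4.35 CPM, and Duox2, which makes hydrogen peroxide at the epithelial surface, 94.5 ± 28.9, 30.3 ± 16.5 and 6.5 ± 2.14 CPM. Scd1, a fatty acid desaturase, Capn1, a calpain, Cyp2u1, a cytochrome, and Aqp8, a water channel, were chosen after their values were seen. Scd1 measured 0.423 ± 0.114, 1.4 ± 1.31 and 40.6 ± 1.31 CPM, Capn1 134 ± 27.5, 132 ± 12.7 and 665 ± 157 CPM, and Cyp2u1 3.64 ± 0.295, 6.31 ± 0.00216 and 20.9 ± 1.45 CPM. Aqp8 stood at 9.06 ± 8.14 CPM in SPF and 6.47 ± 1.67 CPM in GF and had 0 counts in AF. None of these passed edgeR's test over all genes, with adjusted p values in AF versus SPF from 0.0965 for Cyp2u1 to 0.428 for Abca1. Lyz1, a Paneth cell lysozyme also chosen after its values were seen, measured 9.53 CPM in SPF replicate 4 and 308 to 2086 CPM in the other libraries.

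Class II transcripts in GF replicate 3 lay near the SPF level, Cd74 at 220.2 CPM, and in GF replicate 1 far below it, at 10.2 CPM. Material of female mice like those of the SPF libraries, mixed into GF replicate 3, is argued against as the whole source. Xist allows a share of 13.1%. Cd74 was 4.41 times the 49.9 CPM that this share allows, a level of at most 60.6 CPM over single SPF libraries. Male SPF-like material would add no Xist, so these values cannot bound it. Stronger interferon signalling in that library is a candidate explanation. The interferon list lay 1.04 higher (SE 0.108 of the median log2 difference), with 42 of 42 genes higher. This SE covers the spread over genes that move together, not between libraries, and the list lay 0.505 higher in SPF replicate 4 than in SPF replicate 3. These values cannot tell the epithelium from the lymphocytes whose markers were also higher in GF replicate 3. The AF mean lay 0.44 above GF replicate 1 too (36 of 42 genes), at lower class II levels. Antigen-presenting immune cells stay open: the summed CPM of 12 B lineage and myeloid genes, markers of cells that an epithelial sort would mostly remove, was 2.36 times higher (30.5 against 12.9 CPM), far below the 21.6 times of Cd74, while SPF replicate 4 had Cd74 at 329 CPM with a sum of 14.5 CPM.

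In AF, Isx was low with Bco1 and Scarb1 high. A loss of proximal cells is argued against as the source of the low Isx. The proximal list had a median of 0.23 in AF versus GF (SE 0.163), where such a loss would lower all its genes. The distal list had a median of -0.38, and a shift toward a more proximal make-up was not tested. A shift in crypt and villus make-up is argued against too, by the crypt scores. Those of AF replicates 2 and 3 (0.058 and 0.668) lay between those of GF replicates 3 and 1 (-0.133 and 1.26). A covariate so alike in both groups can move AF versus GF little, so the fit with it adds no support of its own. In that fit Isx had a log2 fold change of -6.28 (edgeR adjusted p = 4.86e-04), Bco1 of 6.24 (edgeR adjusted p = 0.00677) and Scarb1 of 5.81 (edgeR adjusted p = 0.00107). Lower retinoic acid signalling, which induces Isx and could follow from the AF diet, stays open, since 3 of 8 genes that retinoic acid induces were tested, with a median of -0.15 (SE 0.0463). The vitamin A content of the diets is not given in the sources used here, and a biological effect of food antigens themselves was not tested apart from the diet.

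Clock genes stood apart between SPF and the 2 other groups. Collection of the groups at different times of day may account for this: 12 of 14 clock genes had the antiphase sign in GF versus SPF (7 of 9 E-box genes higher and 5 of 5 ROR element genes lower in GF), and 13 of 14 in AF versus SPF. A change of the epithelial clock without a microbiota predicts like signs, and time of day, sex and group cannot be told apart here, since sex-linked transcripts and date-like marks differ with the groups.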
